A study of Mus musculus with 11 samples.

How the data were processed

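RNA of whole ovaries of wild-type mice was extracted with Trizol and a column clean-up with DNase digestion, and libraries were made with a stranded Illumina mRNA kit, per the labels' protocols. The deposited table holds raw counts per gene, 1 column per library, which per the submitters' processing notes came from a workflow naming FastQC, cutadapt, STAR, HTSeq and the mouse build mm10. Versions, the gene annotation and the strand setting of the counting are not given in the sources used here. Without the strand setting, reads of overlapping or antisense genes cannot be assigned with certainty, and counts of near-identical genes (immunoglobulin and MHC genes, C4b, Hspa1a and Hspa1b) are uncertain.

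The table lists 54232 genes with symbols, coordinates and identifiers, of which 16474 had no count in any library. Of its identifiers, 54165 were found in GENCODE release M21 and 52873 (97.6%) had identical coordinates there. Coordinates are given as in the table. A symbol was shared by more than 1 identifier for 96 symbols.

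Libraries were grouped by age from the sample titles. Total counts ranged from 5231724 to 33407509, and shallow libraries carry more counting error for genes of low counts. Before averaging, each pair of libraries of the same age was compared by a chi-square test of counts over genes. For 18 month replicates 3 and 4 it was 1.10 per gene, against 35.04 for the next pair and 129 for the highest. With every library thinned to 5231724 counts these values were 1.09, 8.50 and 32.1. The 2 libraries were summed and used as 1 sample, after the data were examined, since the design fixed before that had 11 separate libraries.

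Genes were kept by edgeR's filterByExpr, which left 20331. Counts were scaled by TMM and tested with edgeR's quasi-likelihood F-test (glmQLFit with robust estimation, edgeR 4.0.16 in R 4.3.3), two-sided, with all 3 ages in 1 model, at a Benjamini-Hochberg adjusted p of 0.05. The common biological coefficient of variation was 0.32 with 7 residual degrees of freedom. The SE of a log2 fold change was computed as its size over the square root of F. CPM values are means over samples with TMM factors, and the principal components used log2 CPM with a prior count of 1. List means per sample in the closing tests used log2 CPM with a prior count of 2.

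The comparisons, tests, 35 gene lists and most alternatives were fixed before the data were examined. The lists hold 421 distinct genes, of which 420 were in the table and 391 were tested. Lists with at least 3 tested members were tested with camera (limma 3.58.1) at a preset correlation of 0.01, two-sided and adjusted over the lists, and again with an estimated correlation and with fry. Members were also counted after adjustment over the list alone. Shares of total counts were compared with exact two-sided permutation tests.

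Named genes followed a rule. Per comparison it took up to 6 genes that rose and 6 that fell with the smallest adjusted p, among called genes with a log2 fold change of at least 1 in size, a mean of at least 5 CPM in either group, groups that did not overlap and an established symbol. It also took the 2 members of each list with the smallest adjusted p, and the most abundant oocyte and immunoglobulin member. Genes outside the rule are said to be chosen after their values were seen. Some results for single genes are not reported here.

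Replicate numbers were checked for pairing by the correlation of deviations from the age means. For 18 and 24 months it was 0.389, 0.280 and 0.147 in the 3 same-numbered pairs, all above 0.1, so these numbers were treated as pairing the samples of that comparison and the value with a replicate block stands beside it. Different-numbered pairs of these ages gave -0.327 to -0.0800, except 0.135 for 18 month replicate 2 with 24 month replicate 3. That value also lies above 0.1, and deviations from a mean of few samples are not independent of each other, so the pairing is uncertain. The labels do not say what the numbers share.

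Alternatives were DESeq2's size factors, library totals alone, no or a stricter count filter, a replicate block, a test against a fold of 1.5, only the ages compared, DESeq2 1.42.0, limma-voom with sample quality weights and leaving out each sample. Keeping all 11 libraries apart, fitting the 2 older ages alone with a block, and counting list members without 24 month replicate 3 were added after the data were examined, as was the simulation for the overlap. A planned simulation kept the real 2 month samples, called no gene in both comparisons (0 in each of 20) and is not used here. DESeq2 gave no adjusted p for 51 tested genes in each comparison with 2 months and for 1234 between 24 and 18 months, which were not counted.

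The test was run on simulated counts with 200 changed genes and 24 more raised 2-fold as a changed list, 3 times per comparison. The calls counted below were those of unchanged genes and those of the 200 in the right direction, without the 24. For 18 against 2 months, over 19876 genes, it recovered 27.7% of 2-fold and 65.7% of 4-fold changes among the 200, and 3.78% of the calls counted were unchanged genes. For 24 against 18 months, over 19909 genes, these were 28%, 55% and 8.12%, and for 24 against 2 months, over 19901 genes, 25.7%, 64% and 6.92%. The changed list was called in 3 of 3 simulations of each comparison and 0 of 102 unchanged lists were. Genes were simulated independently of each other, while the oocyte list had an estimated correlation of 0.821 between 18 and 2 months. The simulation thus cannot show how often lists of correlated genes are called by chance. A library divided at random into 2 parts gave a chi-square per gene of 1.01. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.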

Results

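Whole ovaries of wild-type mice were profiled by bulk RNA sequencing at 3 ages, and the counts of reads per gene were compared between the ages. The series describes its subject as the ovary in young, old and post-reproductive life. The labels gave 4 libraries at 2 months, 4 at 18 months and 3 at 24 months of age. The library names of the 24 month group carried 22 months instead, and those of the 2 month group carried 8 weeks. The groups are named here by the sample labels. Total counts per library lay between 26061630 and 33407509, except for 18 month replicate 3 with 5231724 and 18 month replicate 4 with 8892915.

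The counts of 18 month replicates 3 and 4 differed by about counting noise. Their chi-square per gene was 1.10 over 16253 genes, against 35.04 for the next closest pair of the same age. They were therefore summed and counted as 1 sample, a choice made after the counts were seen, so that all values rest on 4, 3 and 3 samples. The labels do not say whether the samples came from separate animals, and the p-values measure only the spread between these samples.

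The first principal component of log2 CPM (counts scaled to library size) held 53% of the variance and ordered the ages. The 2 month samples lay between -90.5 and -77.0 on it, the 18 month samples between 0.53 and 53.5, and the 24 month samples between 19.7 and 130.1. The 2 older ages overlapped on this axis. Correlations between samples of the same age were 0.974 to 0.984 at 2 months, 0.962 to 0.965 at 18 months and 0.924 to 0.957 at 24 months.

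**Figure D1:**
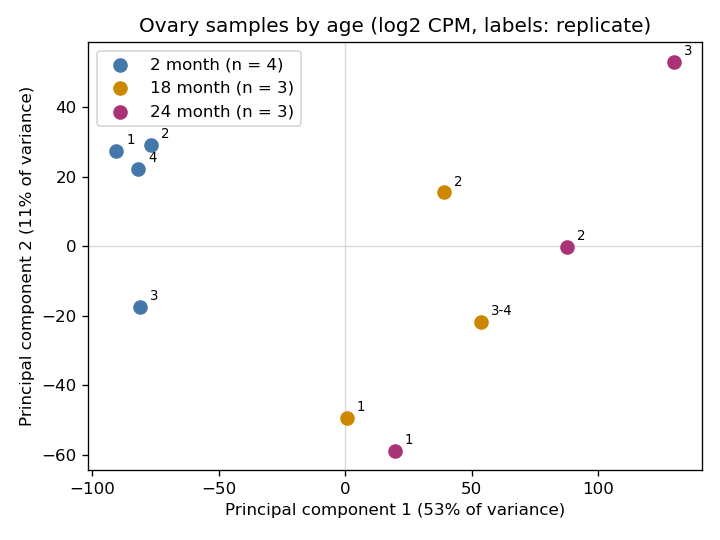
Principal components 1 (53% of variance) and 2 (11% of variance) of log2 CPM, with 1 point per sample coloured by age and labelled by replicate number. The 2 month samples lie between -90.5 and -77.0 on component 1, and 24 month replicate 3 lies farthest from them at 130.1.

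The comparison of 18 months with 2 months asked what differs in the old ovary before the last age sampled. Genes of the oocyte and of cell division were lower at 18 months, and genes of macrophages, T cells, complement, immunoglobulins and the ovarian surface epithelium were higher. Npm2, an oocyte nuclear chaperone, fell from 20.9 ± 6.96 CPM (SD, n = 4) to 3.01 ± 0.893 CPM (n = 3). C4b, a complement component, rose from 7.75 ± 3.21 to 134 ± 81.2 CPM. Csf1r, the receptor for the main macrophage growth factor, rose from 44.7 ± 3.65 to 90.8 ± 6.90 CPM.

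Of the 24 tested genes of the oocyte list, 22 were lower at 18 months and none was higher, and all 24 were lower when adjusted over the list alone. Their median log2 fold change was -3.03 (camera adjusted p = 9.47e-26, and adjusted p = 0.162 with an estimated correlation). Npm2 fell by 2.81 on the log2 scale (SE 0.429, edgeR adjusted p = 0.0117) and Ddx4, a germ cell RNA helicase, fell by 3.00 (SE 0.431). Padi6 (ENSMUSG00000040935), a protein of the oocyte cytoplasm and the list's most abundant member at 2 months, lies on chromosome 4 at 140727355 to 140742643 in mm10 and fell from 122 ± 37.2 to 12.6 ± 6.21 CPM. The genes that fell with the smallest adjusted p included Uchl1, a deubiquitinase, Btg4, which acts in the clearance of maternal mRNA in oocytes, and Gulo, the last enzyme of vitamin C synthesis. Their log2 fold changes were -2.25 (SE 0.282), -2.88 (SE 0.387) and -3.25 (SE 0.430).

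In the cell division list 23 of 24 genes were lower, and 24 when adjusted over the list alone. The median was -1.65 (camera adjusted p = 9.47e-26, and adjusted p = 0.162 with an estimated correlation). Kif11 (ENSMUSG00000012443), a spindle motor, lies on chromosome 19 at 37376403 to 37421859 and fell from 35.7 ± 8.33 to 10.9 ± 2.13 CPM, and Kif14, a kinesin of cytokinesis, fell by 2.13 on the log2 scale (SE 0.288). In the granulosa cell list 4 of 17 genes were lower, 6 when adjusted over the list alone, which also gave 1 gene higher. They included Esr2, the estrogen receptor of granulosa cells, at -1.25 (SE 0.239), and Fshr, the receptor for follicle-stimulating hormone, at -1.53 (SE 0.306). The list had camera adjusted p = 0.00154, and adjusted p = 0.35 with an estimated correlation. None of the 17 cholesterol synthesis genes passed, nor did any when adjusted over the list alone, with a median of -0.45 (camera adjusted p = 0.0165, and adjusted p = 0.678 with an estimated correlation). Neither the theca and steroid synthesis list (median -0.31, camera adjusted p = 0.166) nor the corpus luteum list (median 0.05 with a mean of -0.21, camera adjusted p = 0.571) was called, and none of their 12 and 6 genes passed.

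Among immune lists, 12 of 16 macrophage genes were higher at 18 months, and 15 when adjusted over the list alone (median 1.10, camera adjusted p = 8.77e-16, and adjusted p = 0.157 with an estimated correlation). Csf1r rose by 1.02 on the log2 scale (SE 0.121, edgeR adjusted p = 0.00829) and C1qa, a subunit of complement C1q, by 1.24 (SE 0.146). In the complement list 5 of 10 genes were higher, 6 when adjusted over the list alone (median 0.90, camera adjusted p = 3.03e-08). With every sample in the fit it was the only list whose call held with an estimated correlation, at adjusted p = 0.0282. That call was lost without 24 month replicate 3, a sample of neither age compared (camera adjusted p = 0.0651 with an estimated correlation). C4b (ENSMUSG00000073418) lies on chromosome 17 at 34728380 to 34743882 and rose by 4.11 (SE 0.449), and C1s1, a C1 protease, by 1.55 (SE 0.195). C4b has a near-identical neighbour, so its counts are less certain.

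Genes of lymphocytes were higher as well. In the T cell list 10 of 18 genes were higher, 13 when adjusted over the list alone (median 1.59, camera adjusted p = 1.44e-09, and adjusted p = 0.162 with an estimated correlation). Cd3e, a chain of the T cell receptor complex, rose from 0.4998 ± 0.129 to 4.35 ± 0.824 CPM. In the immunoglobulin constant region list 8 of 10 genes were higher, and all 10 when adjusted over the list alone (median 5.61, camera adjusted p = 3.96e-09, and adjusted p = 0.191 with an estimated correlation). Igkc, the kappa light chain constant region, rose from 4.81 ± 3.34 to 203 ± 111 CPM, and Ighg3 rose by 6.21 (SE 0.880). Reads of immunoglobulin genes, like those of the MHC genes, can be shared between near-identical copies, so their counts are uncertain. In the B cell list 3 of 12 genes were higher, 8 when adjusted over the list alone (median 1.40, camera adjusted p = 0.000278, and adjusted p = 0.275 with an estimated correlation).

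Antigen presentation and signalling lists moved in the same direction. MHC class II had 4 of 9 genes higher (7 adjusted over the list alone, camera adjusted p = 7.42e-05, and adjusted p = 0.273 with an estimated correlation), with H2-Aa at 1.25 (SE 0.248). MHC class I presentation had 4 of 11 genes higher (5 adjusted over the list alone, camera adjusted p = 0.000546, and adjusted p = 0.35 with an estimated correlation). The interferon response list had 2 of 19 higher, Gbp2 and Rsad2 (6 adjusted over the list alone, camera adjusted p = 5.13e-06, and adjusted p = 0.35 with an estimated correlation). The cytokine and inflammasome list had 5 of 11 higher over all genes and over the list alone (camera adjusted p = 0.000271, and adjusted p = 0.227 with an estimated correlation), with the protease Casp1 at 1.39 (SE 0.191). The lymphoid aggregate list had 3 of 8 higher (6 adjusted over the list alone, camera adjusted p = 0.000271, and adjusted p = 0.162 with an estimated correlation), with the B cell chemokine Cxcl13 at 3.46 (SE 0.618). The dendritic cell list had 2 of 9 higher, Xcr1 and Itgax (7 adjusted over the list alone, camera adjusted p = 0.000745, and adjusted p = 0.162 with an estimated correlation). The multinucleated giant cell and lipid-laden macrophage list had 3 of 11 higher (4 adjusted over the list alone, camera adjusted p = 0.0116, and adjusted p = 0.282 with an estimated correlation), with the osteoclast proton pump subunit Atp6v0d2 at 2.31 (SE 0.386). Tbx21 and Eomes, transcription factors of cytotoxic lymphocytes, were the 2 of 12 genes higher in the cytotoxic and NK cell list over all genes and over the list alone (camera adjusted p = 0.0118, and adjusted p = 0.527 with an estimated correlation). Outside the lists, the genes that rose with the smallest adjusted p included Fcgr2b, an inhibitory receptor for IgG, Pla2g2d, a secreted phospholipase, and Il33, an alarmin cytokine, at 1.93 (SE 0.150), 3.54 (SE 0.383) and 2.59 (SE 0.325).

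In the surface epithelium list 6 of 9 genes were higher, 8 when adjusted over the list alone (median 1.96, camera adjusted p = 1.11e-09, and adjusted p = 0.162 with an estimated correlation). Lgals7, an epithelial galectin, rose from 2.50 ± 0.496 to 9.72 ± 0.812 CPM. Lymphatic endothelium had 1 of 6 genes higher, Mmrn1 (6 adjusted over the list alone, camera adjusted p = 0.00168, and adjusted p = 0.275 with an estimated correlation). Sertoli cell genes had 2 of 7 higher over all genes and over the list alone (camera adjusted p = 0.0342, and adjusted p = 0.275 with an estimated correlation), among them the transcription factor Sox9 at 2.60 (SE 0.635). Collagen and matrix had 2 of 20 higher over all genes and over the list alone, the small proteoglycans Dcn and Lum (camera adjusted p = 0.032, and adjusted p = 0.671 with an estimated correlation). Neutrophil had 1 of 4 higher, Csf3r (3 adjusted over the list alone, camera adjusted p = 0.0344, and adjusted p = 0.372 with an estimated correlation). In the oviduct epithelium list, a check for attached oviduct, 1 of 10 was higher over all genes and over the list alone, Pax8, at 22.04 ± 26.3 CPM at 18 months (camera adjusted p = 0.0215, and adjusted p = 0.584 with an estimated correlation). The immediate early and heat shock list, a check for handling, was not called (camera adjusted p = 0.417), but 3 of its 9 genes were lower, and 3 lower and 1 higher when adjusted over the list alone. They were Dnajb1 (-1.15, SE 0.189), Hspa1a (-2.93, SE 0.720) and Hspa1b (-2.33, SE 0.611), the last of them named after its values were seen.

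By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 1228 genes were higher and 1121 lower at 18 months than at 2 months among 20331 tested, 925 and 583 of them by at least 2-fold. The split of calls depended on scaling, with 52.3% of calls higher under TMM factors and 66.7% with library totals alone. The total of 2349 genes fell to 382, 614 and 687 without 2 month replicate 1, 2 or 4, to 730 without 18 month replicate 2 and to 375 without the summed 18 month sample. The calls of Dnajb1, Hspa1a, Hspa1b, Padi6, Esr2, Fshr, Igkc, H2-Aa, Gbp2, Rsad2, Xcr1, Itgax, Tbx21, Eomes, Mmrn1, Sox9, Lum, Csf3r and Pax8 were lost in at least 1 of these 5 fits. The list calls of cholesterol synthesis, collagen and matrix and Sertoli cell were each lost without 2 month replicate 3 or 18 month replicate 2 (adjusted p = 0.082 to 0.251). The cytotoxic and NK cell call was lost without 2 month replicate 4 or 18 month replicate 1 (adjusted p = 0.0598 and 0.115), and the giant cell call without 18 month replicate 1 (0.0862). The oviduct epithelium call was lost without the summed 18 month sample (adjusted p = 0.0844). The neutrophil call was lost without 2 month replicate 2, 18 month replicate 1, the summed 18 month sample or 24 month replicate 1 (adjusted p = 0.0552 to 0.123).

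The comparison of 24 months with 18 months asked what differs between the 2 older ages. As lists, cholesterol synthesis, corpus luteum and oocyte genes were lower at 24 months, and MHC class I presentation, interferon response and mast cell genes were higher, but only by the preset correlation of camera. With an estimated correlation (adjusted p = 0.214 to 0.803) and with fry none of these lists was called, and no member passed over all genes. A single gene passed the test over all genes. Ptpn5 (ENSMUSG00000030854), a protein tyrosine phosphatase on chromosome 7 at 47077795 to 47133684, rose from 2.20 ± 0.637 CPM (n = 3) to 14.1 ± 0.493 CPM (n = 3), a log2 fold change of 2.70 (SE 0.269, edgeR adjusted p = 0.0372).

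In the cholesterol synthesis list no gene passed over all genes and 10 of 17 were lower when adjusted over the list alone (median -1.25, camera adjusted p = 6.55e-21, and adjusted p = 0.498 with an estimated correlation). Dhcr7 (ENSMUSG00000058454), a late enzyme of cholesterol synthesis on chromosome 7 at 143823145 to 143848410, was at 717 ± 162 CPM at 18 months and 148 ± 92.9 at 24 months, a log2 fold change of -2.28 (SE 0.452, edgeR adjusted p = 0.387). In the corpus luteum list none of 6 genes passed over all genes and 5 were lower when adjusted over the list alone (median -1.46, camera adjusted p = 3.27e-07, and adjusted p = 0.214 with an estimated correlation). Ptgfr, the prostaglandin F receptor through which luteal regression is triggered, was at 1587 ± 699.8 and 417 ± 375 CPM. Star, the protein that carries cholesterol into mitochondria for steroid synthesis (ENSMUSG00000031574), lies on chromosome 8 at 25806555 to 25815982. It was at 6735 ± 1834 CPM at 18 months and 1100 ± 472 CPM at 24 months, a log2 fold change of -2.61 (SE 0.487, edgeR adjusted p = 0.387). Its theca and steroid synthesis list had none of 12 genes past the threshold and 1 lower when adjusted over the list alone (camera adjusted p = 0.00494, and adjusted p = 0.803 with an estimated correlation).

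None of the 24 oocyte genes passed over all genes or over the list alone, with a median of -1.26 (camera adjusted p = 7.36e-12, and adjusted p = 0.737 with an estimated correlation). Padi6 was at 12.6 ± 6.21 and 4.47 ± 4.62 CPM. No gene passed in the cell division list (median -0.33, camera adjusted p = 0.000712, and adjusted p = 0.803 with an estimated correlation) or the granulosa cell list (median -0.12, camera adjusted p = 0.0382, and adjusted p = 0.803 with an estimated correlation), nor over either list alone.

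Among the lists higher at 24 months, no mast cell gene passed over all genes and 4 of 5 did when adjusted over the list alone (median 5.57, camera adjusted p = 0.000213, and adjusted p = 0.569 with an estimated correlation). Cpa3, a mast cell carboxypeptidase, was at 0.381 ± 0.2798 CPM at 18 months and 19.7 ± 19.0 CPM at 24 months. In MHC class I presentation (median 0.65, camera adjusted p = 7.2e-05, and adjusted p = 0.737 with an estimated correlation) and the interferon response (median 0.74, camera adjusted p = 6.7e-05, and adjusted p = 0.803 with an estimated correlation) no gene passed over all genes or over the list alone. Psmb8, an immunoproteasome subunit, was at 20.4 ± 3.03 and 32.1 ± 3.38 CPM. The oviduct epithelium list was higher (median 3.15, camera adjusted p = 0.0208, and adjusted p = 0.803 with an estimated correlation) and the erythroid list lower (median -1.91, camera adjusted p = 0.0183, and adjusted p = 0.803 with an estimated correlation), with no gene past the threshold over all genes or over either list alone. Ovgp1, the secreted glycoprotein of oviduct epithelium, was at 381 CPM in 24 month replicate 3 and at 11.9 CPM or less in every other sample.

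By edgeR 1 gene was higher and 0 were lower at 24 months than at 18 months, with 2108 genes at an unadjusted p under 0.05. DESeq2 called 79 higher and 115 lower, among them Star (adjusted p = 1.44e-05), Dhcr7 (0.000238) and Cpa3 (0.0108), limma-voom 1 and 0, and edgeR called 0 and 0 with the replicate number as a block, with 1877 genes at an unadjusted p under 0.05. The call of Ptpn5 was lost with the block, with library totals alone, and when the 2 ages were fitted alone. It was also lost without 2 month replicate 1, 2 or 4, 18 month replicate 1 or 2, or any 24 month sample, at a log2 fold change of 2.50 to 2.92 and adjusted p up to 0.524 over the settings tried. Without 24 month replicate 3 the oviduct list was no longer called (median 0.14, adjusted p = 0.796), nor were theca and steroid synthesis (median -0.05, adjusted p = 0.594) and cell division (median -0.10, adjusted p = 0.36). In that fit the cholesterol synthesis list stayed lower (median -0.91, adjusted p = 4.8e-15), and the immunoglobulin (adjusted p = 0.00105), T cell (0.0173) and plasma cell (0.0308) lists were called lower, none of these 4 with an estimated correlation (adjusted p = 0.67 for each). Collagen and matrix was called higher there (camera adjusted p = 0.0357), but not with an estimated correlation (adjusted p = 0.785). The granulosa cell call was lost without 18 month replicate 2, the summed 18 month sample or 24 month replicate 2 (adjusted p = 0.074 to 0.961). The erythroid call was lost without 18 month replicate 1 or 24 month replicate 2 (adjusted p = 0.0541 and 0.144), and the oviduct call also without 18 month replicate 1 (0.152). Without 18 month replicate 1, 9 lists were called higher in place of 4.

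The comparison of 24 months with 2 months spanned the whole series. Every tested gene of the oocyte and cell division lists fell and every macrophage gene rose. Genes of cholesterol synthesis fell, and most genes of the interferon response and of MHC class I and class II presentation rose. Star fell from 13260 ± 6069 CPM (n = 4) to 1100 ± 472 CPM (n = 3), and C4b rose from 7.75 ± 3.21 to 176 ± 58.0 CPM.

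All 24 oocyte genes were lower over all genes and over the list alone (median -4.33, camera adjusted p = 5.41e-25, and adjusted p = 0.262 with an estimated correlation). Padi6 fell from 122 ± 37.2 to 4.47 ± 4.62 CPM (log2 fold change -4.79, SE 0.719, edgeR adjusted p = 0.00278), and Sohlh1, a transcription factor of early oocytes, fell by 3.78 on the log2 scale (SE 0.463). All 24 cell division genes were lower over all genes and over the list alone (median -2.01, camera adjusted p = 2.1e-21, and adjusted p = 0.275 with an estimated correlation), with Cenpe, a kinetochore motor, at -2.18 (SE 0.283). In the granulosa cell list 7 of 17 genes were lower and 1 higher, over all genes and over the list alone (camera adjusted p = 0.000694, and adjusted p = 0.291 with an estimated correlation). The gene that rose was Nr0b1, a nuclear receptor that represses steroid-synthesis genes, at 2.21 (SE 0.589), named after its values were seen.

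Cholesterol synthesis had 15 of 17 genes lower over all genes and over the list alone (median -1.72, camera adjusted p = 6.07e-10, and adjusted p = 0.275 with an estimated correlation). Dhcr7 fell from 1031 ± 390 to 148 ± 92.9 CPM (log2 fold change -2.80, SE 0.448, edgeR adjusted p = 0.00332) and Nsdhl, a sterol dehydrogenase, fell by 2.02 on the log2 scale (SE 0.378). In the theca and steroid synthesis list 4 of 12 genes were lower over all genes and over the list alone (camera adjusted p = 0.0144, and adjusted p = 0.498 with an estimated correlation). They included Star (-3.59, SE 0.496), the mitochondrial electron carrier Fdx1 (-1.60, SE 0.427) and Scarb1, a receptor for high-density lipoprotein (-1.78, SE 0.559), the last of them named after its values were seen. The list had no called gene among its enzymes of steroid synthesis. In the corpus luteum list 3 of 6 genes were lower, 4 when adjusted over the list alone (camera adjusted p = 0.00363, and adjusted p = 0.275 with an estimated correlation). They were Parm1 (-1.67, SE 0.265), Ptgfr (-1.92, SE 0.594) and Akr1c18, the enzyme that breaks down progesterone (-5.64, SE 1.83), the last of them named after its values were seen.

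**Figure D2:**
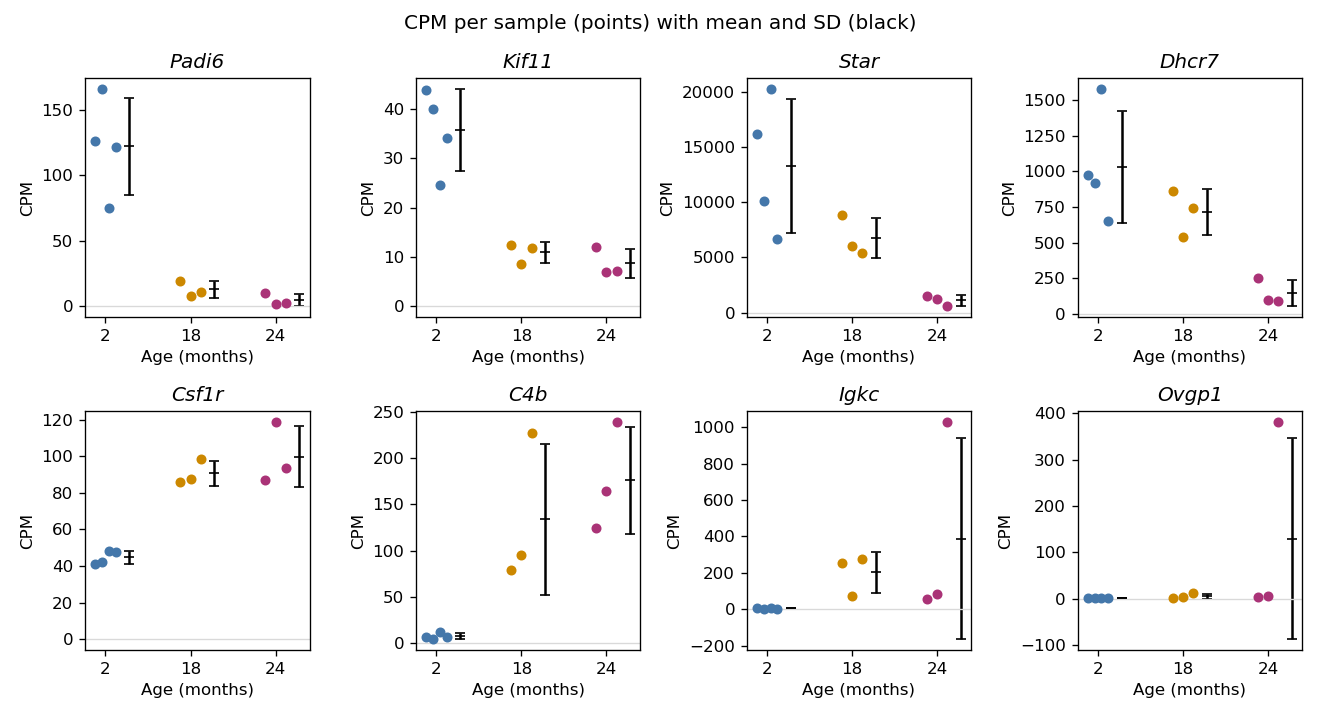
CPM of 8 genes by age in months, with 1 point per sample and the mean with its SD in black (n = 4, 3 and 3), on linear axes that differ between genes. Padi6, Kif11, Star and Dhcr7 lie lower at 24 months than at 2 months in every sample, Csf1r and C4b lie higher, and the highest values of Igkc and Ovgp1 come from 24 month replicate 3 (381 CPM for Ovgp1).

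All 16 macrophage genes were higher over all genes and over the list alone (median 1.23, camera adjusted p = 1.36e-11, and adjusted p = 0.26 with an estimated correlation). Csf1r (ENSMUSG00000024621) lies on chromosome 18 at 61105572 to 61132149 and rose by 1.16 on the log2 scale (SE 0.121, edgeR adjusted p = 0.00138). The interferon response list had 15 of 19 genes higher, 16 over the list alone (median 1.83, camera adjusted p = 5.47e-08, and adjusted p = 0.275 with an estimated correlation), with Rsad2, an antiviral enzyme, at 3.90 (SE 0.655). MHC class I presentation had 9 of 11 higher over all genes and over the list alone (camera adjusted p = 4.14e-06, and adjusted p = 0.275 with an estimated correlation), with Psmb8 at 1.43 (SE 0.189) and Psmb9 at 1.56 (SE 0.231). MHC class II had 8 of 9 higher over all genes and over the list alone (camera adjusted p = 6.09e-05, and adjusted p = 0.275 with an estimated correlation). Complement had 5 of 10 higher, 6 over the list alone (median 1.28, camera adjusted p = 4.14e-06, and adjusted p = 0.0712 with an estimated correlation), with C4b at 4.51 (SE 0.455). Cytokine and inflammasome had 6 of 11 higher, 7 over the list alone (camera adjusted p = 0.00198, and adjusted p = 0.275 with an estimated correlation). Dendritic cell had 5 of 9 higher, 7 over the list alone (camera adjusted p = 0.000863, and adjusted p = 0.262 with an estimated correlation). In the giant cell and lipid-laden macrophage list 5 of 11 genes were higher and 1 was lower over all genes and over the list alone (camera adjusted p = 0.0101, and adjusted p = 0.291 with an estimated correlation). Gpnmb, a glycoprotein of lipid-laden macrophages, rose by 3.48 (SE 0.593), and the gene that fell was Spp1, a secreted matrix protein, at -3.40 (SE 1.12), named after its values were seen.

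Lymphocyte lists were higher at 24 months, with large differences between samples. T cell had 14 of 18 genes higher and 1 lower over all genes and over the list alone (median 1.69, camera adjusted p = 1.6e-05, and adjusted p = 0.275 with an estimated correlation). The gene that fell, Cd28, a costimulatory receptor, was at -4.05 (SE 1.16) and was named after its values were seen. Immunoglobulin constant region had 9 of 10 higher over all genes and over the list alone (median 5.93, camera adjusted p = 2.03e-05, and adjusted p = 0.289 with an estimated correlation), and Igkc was at 389 ± 553 CPM at 24 months. The median of this list was 2.94 without 24 month replicate 3. B cell had 8 of 12 higher, 11 over the list alone (camera adjusted p = 0.000863, and adjusted p = 0.302 with an estimated correlation). Lymphoid aggregate had 5 of 8 higher over all genes and over the list alone (camera adjusted p = 0.00326, and adjusted p = 0.275 with an estimated correlation). Cytotoxic and NK cell had 2 of 12 higher over all genes and over the list alone, Eomes and Tbx21 (camera adjusted p = 0.00882, and adjusted p = 0.443 with an estimated correlation). Of all tested genes 3906 of 20331 were higher, a share no smaller than that of this list. Mast cell had 4 of 5 higher over all genes and over the list alone (camera adjusted p = 0.0417, and adjusted p = 0.422 with an estimated correlation), with Cpa3 at 5.08 (SE 1.22).

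Surface epithelium had 6 of 9 genes higher, 7 over the list alone (camera adjusted p = 2.03e-05, and adjusted p = 0.275 with an estimated correlation), with the keratin Krt19 at 2.51 (SE 0.321). Lymphatic endothelium had 3 of 6 higher over all genes and over the list alone (camera adjusted p = 0.0377, and adjusted p = 0.43 with an estimated correlation). Sertoli cell had 6 of 7 higher, 7 over the list alone (camera adjusted p = 0.00786, and adjusted p = 0.275 with an estimated correlation), with Sox9 at 2.94 (SE 0.640). Oviduct epithelium had 9 of 10 higher, 10 over the list alone (median 5.75, camera adjusted p = 0.00786, and adjusted p = 0.485 with an estimated correlation). In 24 month replicate 3, 9 of these 10 genes stood at least 4 times above the highest 2 month sample. Without this sample 1 of 10 oviduct genes was called (median 2.07, adjusted p = 0.0544). Of all genes called with every sample, 3999 of 7120 were called the same way in that fit. Among called list members, Sertoli cell kept 2 of 6, T cell 7 of 15 and immunoglobulin 6 of 9. B cell kept 3 of 8, corpus luteum 1 of 3 and cholesterol synthesis 10 of 15. Macrophage kept 12 of 16, interferon response 14 of 15, MHC class I 8 of 9, oocyte 23 of 24 and cell division 22 of 24.

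**Figure D3:**
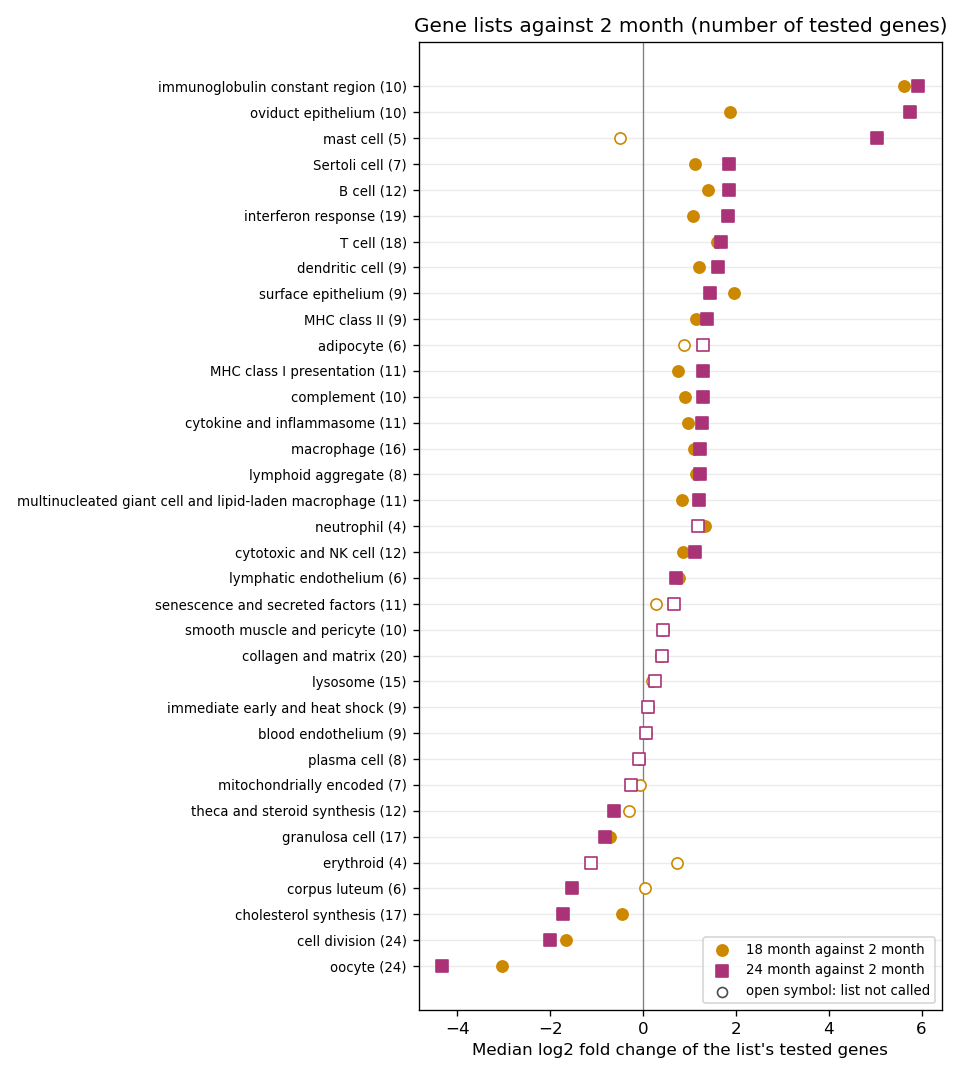
Median log2 fold change of each gene list against 2 months, with circles for 18 months and squares for 24 months, filled where camera called the list, and the number of tested genes in brackets. The oocyte list lies lowest at -3.03 and -4.33, and the immunoglobulin list highest at 5.61 and 5.93. Without 24 month replicate 3 the immunoglobulin median at 24 months is 2.94, below that of mast cell at 5.075.

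By edgeR 3906 genes were higher and 3214 lower at 24 months than at 2 months, 2728 and 1233 of them by at least 2-fold. The genes with the smallest adjusted p were Cd44, a hyaluronan receptor, which rose from 15.2 ± 1.88 to 48.9 ± 1.24 CPM, and on the lower side Pramef12, at -4.10 (SE 0.424), and Lamc3, a laminin chain, at -1.36 (SE 0.142). Of the calls, 54.9% were higher under TMM factors and 73% with library totals alone. The total of 7120 genes fell to 4537 without 2 month replicate 1, to 4656 without 24 month replicate 2 and to 4283 without 24 month replicate 3. The theca and steroid synthesis call was lost without 2 month replicate 3 or 24 month replicate 3 (adjusted p = 0.051 and 0.1). The mast cell call was lost without 2 month replicate 3 or 4 or 24 month replicate 1 or 3 (adjusted p = 0.0503 to 0.17). Lymphatic endothelium was not called without 2 month replicate 4 or 24 month replicate 1 or 2 (adjusted p = 0.0593 to 0.128), nor cytotoxic and NK cell without 24 month replicate 1 (0.0613). Among the genes named for this comparison, Fdx1 lost its call without 24 month replicate 2 and Nr0b1 without 24 month replicate 3, and Scarb1, Ptgfr, Akr1c18, Spp1 and Cd28 each lost it without 2 month replicate 1 and without 24 month replicate 3, among other samples.

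The 2 comparisons against 2 months shared most of the genes called at 18 months. Of the 2349 genes called at 18 months, 2215 (94.3%) were called in the same direction at 24 months, 1162 higher and 1053 lower, and 0 in the opposite direction. Independent lists of these sizes would share 235.9 and 177.2 genes. At an unadjusted p under 0.05, 5192 genes went the same way in both, where independent lists would share 1427. In 20 simulations in which all samples, those of 2 months included, came from a common mean, 143 to 196 genes did so (median 160), where independent lists would share 20.3. The shared 2 month samples thus raise the overlap by chance alone, and part of the excess may come from them. The simulation drew all samples independently, so it leaves out any deviation shared by 18 and 24 month samples of the same number. With the 2 month samples split 2 and 2 between the comparisons, the median over 6 assignments was 73 genes (0 to 726), where independent lists would share 5.42. In these splits a median of only 85.5 genes was called at 18 months. The shared count was 376, 603 and 675 without 2 month replicate 1, 2 or 4, of 382, 614 and 687 called at 18 months. It was 714 of 730 without 18 month replicate 2 and 348 of 375 without the summed 18 month sample. The shared count thus fell along with the number of genes called.

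As a share of all counts, the oocyte list made up 0.0709 ± 0.0256% at 2 months (n = 4), 0.0112 ± 0.00327% at 18 months (n = 3) and 0.00744 ± 0.00511% at 24 months (n = 3). The immunoglobulin list made up 0.00162 ± 0.000633%, 0.0464 ± 0.0268% and 0.1003 ± 0.144%. The oviduct epithelium list made up 0.00199 ± 0.000282%, 0.00748 ± 0.00460% and 0.0400 ± 0.0576%. In exact two-sided permutation tests over 7 lists and 3 comparisons, no share passed the adjustment, and the smallest adjusted p was 0.12. The smallest unadjusted p these designs allow is 0.0286 against 2 months and 0.1 between 24 and 18 months. Against 2 months, the immunoglobulin and oviduct shares at both older ages and the adipocyte share at 24 months reached that smallest p. With so few splits the adjustment over all these tests could hardly be passed, so failing it does not show that shares were alike. The tests between 24 and 18 months did not use the replicate numbers as pairs. The immunoglobulin difference between 24 and 18 months was 0.0539% and turned to -0.0295% without 24 month replicate 3, and that of the oviduct list turned from 0.0325% to -0.000665%.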

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

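Among the tests of explanations below, those of dilution, blood, oviduct tissue and fewer steroid-making cells were chosen only after the result was seen. The requirement that a bound be passed by more than the spread was applied to the Pax8 ratio and to the leave-out tests after their values were seen. So was the requirement that the immune differences pass 2 SE without any 1 sample. Both moved verdicts only toward leaving an explanation open. The spread within pairs was used for the cholesterol list because deviations of same-numbered 18 and 24 month samples were positively correlated, although that pairing is uncertain. This spread was also chosen after the values were seen, and it moved 1 verdict toward excluding.

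Of 109 quantities examined in the 2 month group, 3 had a sample whose gap to the nearest other sample exceeded the 95% critical value of Dixon's test, where chance gives about 1 in 20. H2-D1 stood at 76.2 CPM in 2 month replicate 3 against 36.2 to 41.0 in the others (gap 0.88 of the range). Rsad2 stood at 4.02 CPM in the same sample against 1.45 to 1.52 (0.971). The erythroid list took 0.0303% of counts in 2 month replicate 3 against 0.00196% to 0.0045% (0.91).

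By camera's preset correlation 14 immune gene lists were higher at 24 months than at 2 months. All were called by fry (adjusted p up to 0.0368) and none with an estimated correlation (adjusted p = 0.0712 to 0.443). The mean log2 CPM over the 158 distinct tested members of these lists differed by 1.64 (SE 0.232). A loss of other cells would raise every remaining cell type alike. The immune mean rose above that of 25 endothelium and muscle genes by 1.29 (SE 0.432). This passed 2 SE on leaving out any 1 sample as well (2.07 SE at the least). The immune lists were taken because they were higher in these same samples, and the endothelium and muscle lists were not. An excess was thus likely beforehand, and this test cannot exclude a loss of other cells. The immune mean rose above the erythroid genes by 2.18 (SE 0.967), but by 1.55 (SE 0.788), under 2 SE, without 2 month replicate 3, the erythroid outlier, and by as little as 1.51 SE without other samples, so blood left in the tissue stays open. Without 24 month replicate 3 the immune mean itself differed by 1.47 (SE 0.153), so that sample alone does not account for it. More immune cells, or more expression per cell with age, may both underlie it, and neither was tested.

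Oviduct epithelium genes were high in 24 month replicate 3. There 9 of 10 tested members stood at least 4 times above the highest 2 month library, with Ovgp1 at 381 CPM (159 times), Foxj1 at 190 CPM (91.8 times) and Pax8 at 69.5 CPM (168 times), while Sox17 stood at 1.98 times. Oviduct tissue in that sample stays open, since these genes define the pattern and their count restates it. Cells that carry Pax8 in other old samples stay open as well, since the log2 ratio of the rest of the list to Pax8 was 0.502, against -2.87 to -0.548 in the 3 other samples with enough Pax8, an upper bound of 0.452 and an SD of 1.17. A change of epithelium within the ovary at this age also stays open, untested.

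The cholesterol synthesis list was lower at 24 months than at 18 months, with a mean difference of -1.38 in log2 CPM over 3 pairs of samples (SE 0.426). The list was called by camera's preset correlation but not with an estimated correlation (adjusted p = 0.498) or fry (0.371), and no member passed over all genes. A lower number of steroid-making cells would lower other genes of such cells alike. A set of 9 genes of steroid synthesis differed by -0.147 (SE 0.483), and the cholesterol list fell below it by -1.23 (SE 0.103). The corpus luteum list, also of steroid-making cells, differed by -1.99 (SE 0.274), as the explanation needs, so this explanation stays open. The pair with 24 month replicate 3 differed most, by -2.23. The other 2 pairs differed by -0.874 and -1.04, a mean of -0.958 (SE 0.0842) that passes 0.5 of the whole difference (-0.691) by more than its SE, which argues against that sample as the whole cause. This SE rests on 2 values, and without pairing the difference was -0.997 (SE 0.578), which passes that bound by less than its SE. Lower cholesterol synthesis per cell with age may underlie it and was not tested.

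Other splits of the same samples were counted. For genes called between 18 and 2 months, 1 of 35 splits, the real one, gave as many as 2349 and the highest other gave 617. Between 24 and 2 months 1 of 35 gave as many as 7120 and the highest other gave 2. Both shares are under 0.05, which argues against chance, but 1 of 35 is the smallest share these splits allow. The shares were not adjusted over the tests, so chance is not excluded. For gene lists the shares were not under 0.05, so chance cannot be excluded there either. Of 35 splits, 2 gave as many as the 23 lists of 18 against 2 months (highest other 24). For 24 against 2 months 4 gave as many as the 24 lists (highest other 25). Between 24 and 18 months 10 splits are too few for a share under 0.05. There 3 splits gave as many as the 1 gene called (highest other 2) and 9 as many as the 11 lists (highest other 20). Of the other splits, 3 part as many of the numbered pairs as the real one and called at most 2 genes and 13 to 19 lists, and 6 part fewer and called at most 20 lists.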

How the results depend on the processing

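Keeping all 11 libraries apart and the fit of the 2 older ages with a block were chosen after seeing the data. Where no cause is named, the cause was not tested. Between 18 and 2 months, 1228 higher and 1121 lower genes became 193 and 120 against a fold of 1.5, 2113 and 1939 with DESeq2, and 1988 and 2012 with 11 libraries. Limma-voom called 1749 lower, library totals 662 lower, and the counts were 220 to 1493 higher and 108 to 1442 lower on leaving out 1 sample, where the fit held fewer samples. Between 24 and 18 months, 1 higher gene became 0 with library totals, against a fold of 1.5 and with only those ages, and 79 with DESeq2, which called 115 lower, and leaving out 1 sample gave 0 to 1 in each direction. Between 24 and 2 months, 3906 and 3214 became 1619 and 787 against a fold of 1.5, 1869 lower with library totals, and 2395 to 4238 and 1808 to 3274 on leaving out 1 sample. Library totals moved the median log2 fold change of all genes from 0.01 to 0.10, from 0.03 to 0.12 and from 0.03 to 0.22 in these comparisons. The 2215 genes called the same way became 3641 with DESeq2, 3535 with 11 libraries, 73 with the 2 month samples split and 348 to 2500 on leaving out 1 sample. In the split a median of only 85.5 genes was called at 18 months.

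With the replicate number as a block, the genes became 581 higher and 453 lower between 18 and 2 months, 0 higher between 24 and 18 months (also 0 with the 2 ages fitted alone with the block), and 1017 called the same way. The 2 month samples share only numbers with the others (same-number correlations -0.113 to 0.0628). The block ended the list calls of cytotoxic and NK cell (adjusted p = 0.0567) and oviduct epithelium (0.102) between 18 and 2 months and of lymphatic endothelium (0.0588) between 24 and 2 months, and no other list call.

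Camera called 19 lists higher and 4 lower between 18 and 2 months, of which an estimated correlation kept 1 and 0. Leaving out 1 sample gave 16 to 20 and 3 to 5, and fry called 13 and 2. Among the 13 was senescence and secreted factors (fry adjusted p = 0.0267), which camera had not called (adjusted p = 0.119). There fry ended the calls of granulosa cell (adjusted p = 0.0909), cholesterol synthesis (0.401), cytotoxic and NK cell (0.109), giant cell (0.0515), neutrophil and MHC class I (0.0537 each), interferon response (0.0682), collagen and matrix (0.285) and oviduct epithelium (0.232). The 4 and 7 between 24 and 18 months became 0 and 0 with an estimated correlation and with fry, and 4 to 9 and 6 to 8 on leaving out 1 sample. The 18 and 6 between 24 and 2 months became 0 and 0 with an estimated correlation, 20 and 5 with fry, and 15 to 18 and 5 to 7 on leaving out 1 sample. There fry ended the calls of theca and steroid synthesis and oviduct epithelium (adjusted p = 0.0927 each). Fry also called lists higher that camera had not, senescence and secreted factors (adjusted p = 0.0175), lysosome (0.0415) and neutrophil (0.0451). Library totals also ended the calls of Sertoli cell (18 against 2 months, adjusted p = 0.0531), oviduct epithelium (24 against 18 months, 0.0798) and mast cell (24 against 2 months, 0.0841). Under the denominators tried every share of counts moved by less than its SD. Without 24 month replicate 3 the differences of the immunoglobulin and oviduct shares between 24 and 18 months changed sign, from 0.0539% to -0.0295% and from 0.0325% to -0.000665%. Of 140 called values of named genes, 83 were called in every setting and 57 lost the call in at least 1. Calls were lost for 2 with library totals, 26 without a count filter, 34 with the block, 2 with 11 libraries and in 204 of their 1680 fits on leaving out 1 sample, and DESeq2 called 9 values that were not called, all between 24 and 18 months, among them Star, Dhcr7, Cpa3, Parm1, Plin4, Sparc and Cd28. The depth of 18 month replicates 3 and 4 limits what their summed sample can show for genes of low counts.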

Other observations

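Some lists were not called by camera between 24 and 2 months although single members were. Genes outside the naming rule (Irf4, Sdc1, Cdkn2a, Cdkn2b, Ctsl, Sparc, Adipoq, Hspa1a and Hspa1b) were chosen after their values were seen. The plasma cell list had 2 genes higher and 2 lower of 8, over all genes and adjusted over the list alone (median -0.09, camera adjusted p = 0.572). Jchain, the joining chain of secreted IgA and IgM, rose from 1.40 ± 0.942 to 74.5 ± 102 CPM (n = 4 and 3), and Irf4, a transcription factor of plasma cells, rose by 2.29 on the log2 scale (SE 0.527). The log2 fold change of Jchain ranged from 3.49 to 6.27 over the settings tried. Derl3, a protein of the endoplasmic reticulum, and Sdc1, a cell surface proteoglycan also made by epithelia, were at -2.38 (SE 0.341) and -2.03 (SE 0.491). The senescence and secreted factors list had 4 higher and 1 lower of 11 over all genes and over the list alone (camera adjusted p = 0.274). Fry called this list higher (adjusted p = 0.0175), while camera with an estimated correlation did not (adjusted p = 0.422). Cdkn2a, a cell cycle inhibitor, stood at 0.852 ± 0.416, 5.49 ± 2.62 and 2.90 ± 1.41 CPM at 2, 18 and 24 months and was called at 18 months (log2 fold change 2.69, SE 0.522) and at 24 months (1.76, SE 0.515) against 2 months, while its neighbour Cdkn2b was lower at -2.83 (SE 0.900). The 24 month call of Cdkn2a was lost without 2 month replicate 2, 3 or 4 or 24 month replicate 2 or 3, and its 18 month call without 2 month replicate 2 or 4 or 18 month replicate 2. The call of Cdkn2b was lost with all 11 libraries kept apart and without 2 month replicate 1 or 3 or any 24 month sample. Among the other genes named in this part, Ctsl, Lipe, Adipoq, Hspa1a, Hspa1b, Des and Tagln lost their call without 24 month replicate 2, among other samples.

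The lysosome list had 5 higher and 1 lower of 15 over all genes and over the list alone (camera adjusted p = 0.0979). It was called higher by fry (adjusted p = 0.0415), but not by camera with an estimated correlation (adjusted p = 0.579). Ctss, a protease of antigen-presenting cells, rose from 41.9 ± 8.74 to 199.7 ± 54.9 CPM, and Ctsl, another lysosomal protease, fell from 1068 ± 253 to 580 ± 236. The collagen and matrix list had 5 higher and 1 lower of 20 over all genes and over the list alone (camera adjusted p = 0.111), and without 24 month replicate 3 it was called higher by the preset correlation (adjusted p = 0.00351), but not with an estimated correlation (adjusted p = 0.462) or fry (0.0819). Dcn rose from 234.5 ± 46.8 to 1318 ± 352 CPM, while Sparc, a matrix-binding protein, fell from 3389 ± 621 to 1373 ± 536. The adipocyte list had 1 higher and 2 lower of 6, and 3 and 2 adjusted over the list alone (median 1.30 with a camera test pointing down, adjusted p = 0.919). Plin4, a lipid droplet coat protein, had a log2 fold change of -3.12 (SE 0.606). Lipe, the hormone-sensitive lipase that also frees cholesterol in steroid-making cells, fell from 64.1 ± 28.6 to 30.6 ± 8.96, while Adipoq stood under 1 CPM on average at each age. The immediate early and heat shock list had 1 higher and 3 lower of 9, and 2 and 4 adjusted over the list alone (median 0.12 with a camera test pointing down, adjusted p = 0.262). The heat shock genes Dnajb1, Hspa1a and Hspa1b fell, with log2 fold changes of -1.65 (SE 0.193), -2.76 (SE 0.710) and -2.33 (SE 0.609), while Atf3, a stress-induced transcription factor, rose by 1.71 (SE 0.395).

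Vwf was the 1 gene of 9 higher in blood endothelium over all genes and over the list alone (median 0.07 with a camera test pointing down), and Csf3r was the 1 of 4 in the neutrophil list (camera adjusted p = 0.152). The neutrophil list was called higher by fry (adjusted p = 0.0451), but not by camera with an estimated correlation (adjusted p = 0.511). Smooth muscle and pericyte had Des and Tagln higher of 10, and 1 adjusted over the list alone (camera adjusted p = 0.556), and without 24 month replicate 3 it was called higher by the preset correlation (adjusted p = 0.0271) and fry (0.0247), but not with an estimated correlation (adjusted p = 0.318). None of 4 erythroid and none of 7 mitochondrially encoded genes passed between 24 and 2 months (camera adjusted p = 0.556 and 0.274). Mitochondrially encoded genes took 3.25 ± 0.343%, 3.29 ± 0.527% and 3.06 ± 0.12% of counts at 2, 18 and 24 months. The adipocyte list took 0.0556 ± 0.0153%, 0.0335 ± 0.00389% and 0.0136 ± 0.00752%. The erythroid list took 0.0102 ± 0.0134%, 0.0185 ± 0.0187% and 0.0052 ± 0.00425%, and the immediate early and heat shock list 0.0556 ± 0.0162%, 0.0455 ± 0.0195% and 0.0359 ± 0.00777%.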
